A study of Danio rerio with 12 samples.

How the data were processed

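Endothelial cells sorted from flk1:GFP zebrafish embryos at 48 hours after fertilization were profiled in 3 groups, control, miR-126 MO-1 and miR-126 MO-2, with 4 arrays each. RNA was extracted with Trizol, amplified with the NuGen WT-Ovation Pico kit and hybridized to one-colour Affymetrix zebrafish arrays with a biotin label, per the labels. The deposited values are log2 signals of probe sets, made by the authors with Robust Multi-array Average (RMA), which corrects the background and normalizes across arrays. RMA is named in the submitters' processing notes; its version is not given in the sources used here, and the log base was inferred from the values. The 12 arrays had medians from 6.80 to 6.86, lower quartiles from 5.39 to 5.61 and upper quartiles from 8.12 to 8.24, with values from 2.47 to 14.2. The injection status of control replicates 2, 3 and 4 and the meaning of the replicate number are not given in the sources used here.

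The table held 15617 probe sets. The 115 control probe sets were left out of the tests, and the other 15502 were tested with no filter on signal. Probe sets were named through the platform's probe annotation, whose date is not known: 10795 had 1 gene symbol, 135 had several and 4572 had none. Symbols were updated through Entrez gene numbers for 10711 probe sets, which changed 1 symbol. Each of 8793 genes was represented by its probe set with the highest mean signal. Genes are printed by symbol, without the names of their probe sets. Genome positions are not part of these data and are not reported.

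Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group means of the 12 arrays). The comparisons were MO-1 against control, MO-2 against control, the mean of both morpholinos against control, and MO-2 against MO-1, with Benjamini-Hochberg adjustment over the 15502 probe sets of a comparison and a threshold of 0.05; tests were two-sided. The fit had 13.14 degrees of freedom, a median SE of 0.18 log2 for a comparison of 4 with 4 arrays and a median half-width of the 95% interval of 0.40, or 0.34 for both morpholinos together. A fold change in a text value is the difference of group means of log2 values; SE is limma's standard error.

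Gene lists were written before the data were examined, as were the sample groups, the tests and most of the other settings tried. There were 30 lists: vascular lists for the sorted cells, stress and p53 lists for morpholino injection, and markers of other cell types that a sort could hold. Lists with at least 4 measured genes were tested, which made 29; the list of miR-126 host genes and study genes had 1 measured gene, spred1. Each list was compared with all other genes by limma's camera with its preset correlation of 0.01 and again with the correlation estimated for each list, and p was adjusted over the 29 lists of a comparison. With an estimated correlation 0 lists were called in each of the 4 comparisons, and the lowest adjusted p was 0.429 with MO-1, 0.821 with MO-2, 0.73 with both together and 0.392 between the morpholinos. List scores are means over the genes of a list after each gene was centred on its mean over the 12 arrays. Members were also tested adjusted over the list alone. Over all arrays, the median, mean and test of a list differ in sign only among lists that were not called. Skeletal muscle and glycolysis lists share 2 measured genes. The ribosomal list, taken by name prefix, holds rps27l and rps19bp1, the oxidative phosphorylation list holds assembly factors, and the glucagon gene gcga stood in the eye and lens list by error. Motile cilia, pronephros and ionocyte, endocrine pancreas, exocrine pancreas and liver secreted protein lists were added after the smallest p-values were seen, without the genes seen there.

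Genes were named by a fixed rule: spred1, the genes with the largest changes among those past the threshold, and for each list mentioned up to 2 members with the largest change. Since no gene passed, the 5 genes with the smallest p of each comparison were named and are given as not passing. Other genes are said to have been chosen after their values were seen.

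Whether replicate numbers pair the samples was checked on values centred on group means. The 12 pairs of arrays with the same number correlated at 0.223 to 0.626 with a median of 0.425, the 36 pairs with other numbers had a median of -0.17, and 12 of 12 arrays had their best partner under the same number. The replicate number was therefore also used as a block, and blocked values are given where they change a call or move a count by over 1.5 times.

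The tests were tried on simulated data of the same size with 50 genes changed at each fold. Limma recovered 16%, 74%, 92% and 98% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold with MO-1, 10%, 76%, 90% and 98% with MO-2, and 26%, 84%, 92% and 100% with both together. It called 3, 8 and 6 unchanged probe sets in these comparisons and 0 between the morpholinos. Camera called 0 of 29 lists with no simulated change and called a list shifted by 0.3 log2 with either correlation. The simulated genes varied independently of each other and held no pattern by replicate number. These trials therefore do not show how often correlated members or such a pattern lead to false calls.

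Agreement of the morpholinos was given as a correlation and covariance across probe sets. It was set beside 1000 pairs of simulated unchanged groups, and beside splits of the controls, or of the replicate numbers, between the morpholinos. The groups of a simulated pair shared their simulated controls, which were redrawn with them by shuffling the arrays. The count of shared probe sets used 100 simulated pairs. Alternatives were the replicate block, another quantile normalization, median centring of each array, the brighter probe sets only, a trended and robust prior variance, array weights, only the groups compared in the fit, a minimum change of 1.5-fold, the mean of a gene's probe sets, leaving out each array, and leaving out the arrays of each number. The block without the arrays numbered 4, the block with estimated correlations, the calls gained without 1 array with estimated correlations, and the glycolysis list without muscle genes were added after the data were seen. A test of miR-126 seed matches in 3′ untranslated regions was planned and could not be run, since no sequences of these regions were at hand. Scripts used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0.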

Results

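RNA of endothelial cells sorted from zebrafish embryos was measured on 12 one-colour Affymetrix zebrafish arrays. The embryos carried flk1:GFP, a transgene expressed in endothelium, and the GFP-positive cells were collected by flow sorting at 48 hours after fertilization. The groups were control, miR-126 MO-1 and miR-126 MO-2, with 4 biological replicates each. MO-1 and MO-2 are independent morpholinos, antisense oligonucleotides against maturation of the miR-126 precursor. Embryos received 4 ng at the one-cell stage. The label of control replicate 1 says uninjected, and the labels of control replicates 2, 3 and 4 mention no injection. No label names a control oligonucleotide, so a difference from control may also come from the injection itself, which these data do not separate. The series asks which endothelial genes are regulated by miR-126, a microRNA of endothelial cells. The median log2 signal of an array lay between 6.80 and 6.86, and the upper quartile between 8.12 and 8.24. Correlations between arrays ran from 0.944 to 0.992 across 15502 probe sets, which are not independent replicates. The number of arrays limits the precision: the 95% interval of a difference between groups of 4 had a median width of 0.40 log2 to each side.

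Endothelial genes had their lowest signal in the arrays numbered 4 of each group. The pan-endothelial score, the mean of 14 centred endothelial genes, was -0.52 in control replicate 4, -0.93 in MO-1 replicate 4 and -0.87 in MO-2 replicate 4, against values from -0.08 to 0.52 in the other 9 arrays. Against replicates 1 to 3, the median shift of the endothelial genes in these 3 arrays was -1.01 log2, and that of the venous and lymphatic genes was -0.56. Genes of other cell types in the same arrays had median shifts of 1.13 for skeletal muscle, 0.55 for epidermis, 0.09 for neural tissue and 0.07 for mesenchyme. The 3′ signal of the GAPDH and acta1 control probe sets exceeded the 5′ signal by 2.64 to 2.89 log2 in the arrays numbered 4 and by at most 2.46 in the others. The skeletal muscle score varied widely inside every group, with means of -0.23 ± 1.05 in control, -0.21 ± 1.12 with MO-1 and 0.44 ± 0.68 with MO-2 (SD, n = 4 each). The arrays numbered 2 combined high muscle scores of 0.49, 0.76 and 0.79 with endothelial scores of 0.12, 0.36 and 0.39 in control, MO-1 and MO-2.

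**Figure D1:**
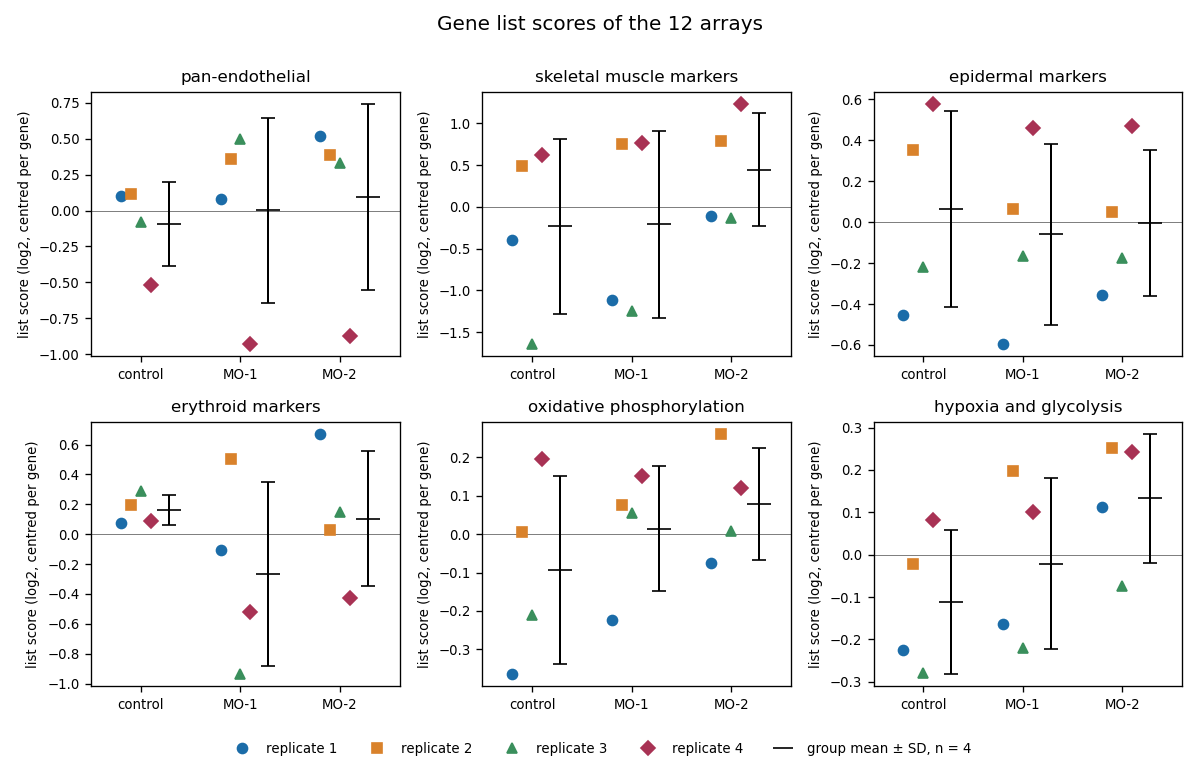
Scores of gene lists on each array, in log2 units relative to the mean of each gene over the 12 arrays, by group; points are arrays, with shape and colour for the replicate number, and the black bar is the group mean with its SD (n = 4). The pan-endothelial scores of the arrays numbered 4 are -0.52, -0.93 and -0.87, below those of the other 9 arrays.

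MO-1 was compared with control to find what differs in sorted endothelial cells after injection of the first oligonucleotide against miR-126 processing. Erythroid genes fell with MO-1: 14 of 15 measured genes had a lower mean than in control, with a median change of -0.40 log2 (adjusted p = 3e-06 by camera, and adjusted p = 0.429 with an estimated correlation). The embryonic globin genes hbbe2 and hbae3 had changes of -1.05 (SE 0.39) and -0.92 (SE 0.47). The erythroid score was 0.16 ± 0.10 in control and -0.27 ± 0.62 with MO-1 (SD, n = 4 each), and it was lower in 3 of 4 pairs of arrays with the same number. Genes of oxidative phosphorylation rose by a median of 0.13, with 65 of 76 higher (adjusted p = 0.000797, and adjusted p = 0.85 with an estimated correlation). The members with the largest changes were cox4i2, a subunit of cytochrome c oxidase, at -0.47 (SE 0.19) and atp5md, a subunit of ATP synthase, at 0.34 (SE 0.19). Neural, epidermal, and liver, gut and yolk lists were called lower with MO-1. Neural genes had a median change of -0.17 with 31 of 43 lower (adjusted p = 0.00674, and adjusted p = 0.817 with an estimated correlation). The change of sox19a, a transcription factor of neural progenitors, was -0.70 (SE 0.29) and that of the synaptic gene snap25a was -0.62 (SE 0.45). Epidermal genes had a median of -0.14 with 25 of 31 lower (adjusted p = 0.00867, and adjusted p = 0.762 with an estimated correlation). The change of anxa1b was -0.51 (SE 0.59) and that of the keratin gene krt5 was -0.44 (SE 0.79). Liver, gut and yolk genes had a median of -0.03, a mean of -0.19 and 26 of 47 lower (adjusted p = 0.00674, and adjusted p = 0.762 with an estimated correlation). The change of fga, the fibrinogen alpha chain, was -1.62 (SE 0.58) and that of ins, the insulin gene, was -1.59 (SE 0.43).

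The VEGF and ERK list and the PI3K list fell with MO-1 by small amounts. The list of VEGF signalling, the ERK pathway and its feedback had a median change of -0.06 with 15 of 23 genes lower (adjusted p = 0.00931, and adjusted p = 0.653 with an estimated correlation). The change of spry4, a feedback inhibitor of receptor tyrosine kinase signalling, was -0.47 (SE 0.20) and that of etv5b, a transcription factor induced by ERK signalling, was -0.34 (SE 0.19). The PI3K, AKT and angiopoietin list had a median of -0.09 with 12 of 18 lower (adjusted p = 0.0261, and adjusted p = 0.429 with an estimated correlation). The change of pik3r3a was -0.34 (SE 0.25) and that of the kinase akt2 was -0.33 (SE 0.18), and the score of the list was lower in 4 of 4 pairs. Axon guidance genes had a median of -0.06 with 22 of 30 lower (adjusted p = 0.0203, and adjusted p = 0.762 with an estimated correlation). The change of the receptor gene robo2 was -0.43 (SE 0.24) and that of epha2a, also a receptor gene, was -0.38 (SE 0.29). Ribosomal protein genes had a median of -0.04 with 53 of 74 lower (adjusted p = 0.0244, and adjusted p = 0.863 with an estimated correlation). The change of rps27l was 0.39 (SE 0.30) and that of rpl10a was -0.18 (SE 0.15). With the replicate number as a block the adjusted p of the ribosomal list was 0.0511. The 14 pan-endothelial genes had a median change of 0.14, with 10 higher, and did not pass (adjusted p = 0.573); fli1rs was at 0.25 (SE 0.27) and lmo2 at 0.21 (SE 0.32). Without the 3 arrays numbered 4, which had the lowest endothelial scores, the endothelial list was called higher, with a median of 0.26 and 12 of 14 genes higher (adjusted p = 0.00018, and adjusted p = 0.55 with an estimated correlation). Without MO-1 replicate 4 alone it was called at 0.40 (adjusted p = 6.98e-05, and adjusted p = 0.72 with an estimated correlation). Its median was reversed, at -0.11 without control replicate 4, -0.06 and -0.07 without MO-1 replicates 2 and 3 and -0.09 without the arrays numbered 3. The arrays numbered 4 stood out by this same score, with shifts from replicates 1 to 3 of -1.245 with MO-1 and -0.5631 in control. Leaving them out, or MO-1 replicate 4 alone, thus raises the difference by itself and gives no support for a rise. The 11 measured genes named as miR-126 targets in the literature had a median change of 0.07, with 6 higher, and did not pass (adjusted p = 0.667); hoxa9b was at 0.34 (SE 0.17) and tom1 at 0.24 (SE 0.19). For spred1, an inhibitor of Ras-ERK signalling described as a target of miR-126, log2 signal was 7.51 ± 0.19 in control and 7.58 ± 0.16 with MO-1 (SD, n = 4 each). That is a change of 0.07 with a 95% interval from -0.25 to 0.38, and its other 3 probe sets had changes of -0.01, -0.32 and 0.14.

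No single gene passed the test with MO-1: limma called 0 of 15502 probe sets, and 172 had an unadjusted p under 0.05, where chance alone gives 775.1. With the replicate number as a block it called 0, with 445 at an unadjusted p under 0.05. Without the block, differences between replicate numbers count as spread, with a median SE of 0.18 against 0.16 with it. That lowers the count of small p-values, so 172 against 775.1 does not measure how many genes changed. The genes with the smallest p, none of which passed (adjusted p = 1), had lower means with MO-1. They were hif1al2, a relative of hypoxia-inducible factor 1 alpha, at -0.64 (SE 0.15), and sst1.1, encoding the hormone somatostatin, at -0.91 (SE 0.24). The others were syncripl, an RNA-binding protein gene, at -0.47 (SE 0.13), ins at -1.59 (SE 0.43) and hapstr1a at -0.63 (SE 0.20). Log2 signal of ins was 10.67 ± 0.39 in control and 9.08 ± 1.04 with MO-1, and that of hif1al2 was 4.69 ± 0.19 and 4.05 ± 0.26 (SD, n = 4 each). The signal of hif1al2 was thus low, below the lower quartiles of the arrays, 5.39 to 5.61. The change of ins was negative in 3 of 4 same-numbered pairs and that of the other 4 genes in 4 of 4. No list member passed when adjusted over the list alone, and 7 did with the replicate number as a block: tfa, apoa2, fgb, fga, fgg, ins and sox19a. Of the 9 list calls, erythroid genes alone were called whichever array was left out, though their median was -0.24 without MO-1 replicate 3, -0.25 without control replicate 2 and -0.80 without MO-1 replicate 2. A single same-numbered pair gave a share of 0.72 of the summed erythroid difference, with an SD of 0.65 over the pairs. Other calls that were kept moved by over 1.5 times. Without control replicate 4 the medians were -0.15 for VEGF and ERK, -0.06 for PI3K, -0.30 for neural genes, 0.22 for oxidative phosphorylation and -0.17 for axon guidance. Without MO-1 replicate 1 they were -0.09 for VEGF and ERK, 0.21 for oxidative phosphorylation, -0.16 for axon guidance, -0.05 for ribosomal genes and 0.01 for liver, gut and yolk genes. Epidermal genes were at -0.25 without control replicate 1 and -0.27 without MO-1 replicate 4, ribosomal genes at -0.02 without control replicate 3 and -0.06 without MO-1 replicate 3. Liver, gut and yolk genes were at -0.01 and -0.05 without control replicates 2 and 3, and at -0.05 and -0.13 without MO-1 replicates 3 and 4. Leaving out control replicate 1 ended 6 calls, with medians of 0.02 for neural genes and 0.03 for oxidative phosphorylation. Leaving out MO-1 replicate 2, 3 or 4 ended 5 each, control replicate 3 ended 3, control replicate 2 or 4 ended 2 each and MO-1 replicate 1 ended 1. Medians were then 0.06 for neural genes without MO-1 replicate 3, 0.02 for ribosomal genes without MO-1 replicate 2 and 0.00 for axon guidance genes without control replicate 3. Epidermal genes were at -0.04 and -0.01 without control replicates 2 and 4 and at 0.05 without MO-1 replicate 1, and the median was 0.08 for oxidative phosphorylation without MO-1 replicate 4. The median of liver, gut and yolk genes turned to 0.04 without MO-1 replicate 2 and 0.01 without control replicate 4. VEGF and ERK were at -0.02 without control replicate 1 or MO-1 replicate 4, and PI3K at -0.06, -0.05 and -0.17 without control replicates 1 and 2 and MO-1 replicate 4. Axon guidance was at -0.03 without control replicate 1 and at 0.00 and -0.04 without MO-1 replicates 2 and 3. The arrays numbered 4 left out together ended the ribosomal call (adjusted p = 0.15) and moved the neural median to -0.39. The medians of kept calls also moved to -0.11 for VEGF and ERK, -0.16 for PI3K, -0.12 for axon guidance and -0.11 for liver, gut and yolk genes.

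MO-2 was compared with control to ask the same of the second oligonucleotide. Skeletal muscle genes rose with MO-2: each of the 32 measured genes had a higher mean, with a median change of 0.63 (adjusted p = 1.66e-07 by camera, and adjusted p = 0.86 with an estimated correlation). The slow myosin heavy chain smyhc1 was at 1.21 (SE 0.60) and the muscle phosphoglycerate mutase pgam2 at 1.17 (SE 0.82). The muscle score was higher in 4 of 4 same-numbered pairs, by 0.29, 0.29, 1.52 and 0.61, so that the pair numbered 3 gave 56.1% of the summed difference. Genes of hypoxia and glycolysis rose with them, by a median of 0.19 with 33 of 40 higher (adjusted p = 1.25e-05, and adjusted p = 0.821 with an estimated correlation), and their score was higher in 4 of 4 pairs. The glycolytic enzymes aldoab and gapdh were at 1.19 (SE 0.80) and 1.02 (SE 0.67). Genes of oxidative phosphorylation rose by a median of 0.18 with 70 of 76 higher (adjusted p = 6.45e-08, and adjusted p = 0.86 with an estimated correlation). The change of cox4i1l was 0.59 (SE 0.44) and that of ndufv2 was 0.49 (SE 0.25).

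Neural genes fell with MO-2, with a median change of -0.26 with 32 of 43 lower (adjusted p = 0.000955, and adjusted p = 0.86 with an estimated correlation). The change of sox19a was -0.61 (SE 0.29) and that of fabp7a, a fatty acid binding protein of radial glia, was -0.60 (SE 0.47). Ribosomal protein genes fell, with a median change of -0.07 and 65 of 74 lower and a lower score in 4 of 4 pairs (adjusted p = 0.000106, and adjusted p = 0.86 with an estimated correlation). The change of rps27l was 0.50 (SE 0.30) and that of rps10 was -0.21 (SE 0.24). Liver, gut and yolk genes had a median change of -0.02, a mean of -0.15 and 27 of 47 lower (adjusted p = 0.034, and adjusted p = 0.86 with an estimated correlation). The change of ins was -1.50 (SE 0.43) and that of fga was -1.32 (SE 0.58). The list of heat shock and early stress fell, with a median change of -0.11 and 22 of 29 lower (adjusted p = 0.034, and adjusted p = 0.821 with an estimated correlation), although the members with the largest changes were the chaperone genes hsp90aa1.1 at 0.92 (SE 0.53) and hspb8 at 0.81 (SE 0.36); with the replicate number as a block its adjusted p was 0.0895. The pan-endothelial genes had a median change of 0.21 with 12 of 14 higher and did not pass (adjusted p = 0.236); plvapb, a protein of endothelial fenestrae, was at 0.46 (SE 0.72) and the endothelial transcription factor erg at 0.35 (SE 0.42). Without the arrays numbered 4 this list was called higher, with a median of 0.35 and 13 of 14 genes higher (adjusted p = 6.97e-05, and adjusted p = 0.473 with an estimated correlation). Without MO-2 replicate 4 alone it was called at 0.47 (adjusted p = 0.000525, and adjusted p = 0.752 with an estimated correlation), and without MO-2 replicate 1 the direction of the test was reversed, with a median of 0.05. In the arrays numbered 4 the score of this list was shifted by -1.286 with MO-2 and -0.5631 in control. Leaving them out, or MO-2 replicate 4 alone, thus raises the difference by itself and gives no support for a rise. The largest changes without the arrays numbered 4 were 0.67 (SE 0.25) for plvapb and 0.62 (SE 0.25) for lmo2. The gene kdrl, the VEGF receptor whose promoter drives the transgene, was at 0.60 (SE 0.20) and was chosen after its values were seen. None of these genes passed limma's test (adjusted p = 0.922 each), and over all arrays kdrl was at 0.33. The literature targets of miR-126 had a median change of 0.10 and did not pass (adjusted p = 0.0762), with the chemokine gene cxcl12b at 0.68 (SE 0.51) and hoxa9b at 0.42 (SE 0.17). They were called without control replicate 1, at 0.14, and without MO-2 replicate 4, at 0.25, and neither call held with an estimated correlation (adjusted p = 0.831 and 0.752). Log2 signal of spred1 was 7.69 ± 0.19 with MO-2 (SD, n = 4), a change of 0.18 (SE 0.15), and its other 3 probe sets had changes of -0.15, -0.08 and -0.04.

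With MO-2 limma called 0 of 15502 probe sets, and 345 had an unadjusted p under 0.05; with the replicate number as a block it called 0, with 947 at an unadjusted p under 0.05 and a smallest adjusted p of 0.132. The genes with the smallest p, none of which passed (adjusted p = 1), were sst1.1 at -1.09 (SE 0.24), syncripl at -0.53 (SE 0.13), si:ch211-250g4.3 at -1.17 (SE 0.28), hnrnpdl, an RNA-binding protein gene, at -0.59 (SE 0.15) and fxyd6l, of a family that regulates ion transport, at 0.43 (SE 0.12). Each had the same sign in 4 of 4 same-numbered pairs. Log2 signal of sst1.1 was 6.37 ± 0.35 in control and 5.28 ± 0.34 with MO-2, and that of hnrnpdl was 10.53 ± 0.15 and 9.94 ± 0.28 (SD, n = 4 each). Without the arrays numbered 4, 1 probe set was called, that of pierce1, a gene of motile cilia, with a change of 1.49 (SE 0.15; adjusted p = 0.0247). It was chosen after its values were seen, and its change over all arrays was 1.14 (SE 0.39). With the replicate number as a block as well, 7 probe sets were called, 5 higher and 2 lower. They were those of pierce1, slc12a3 at 1.41, penkb at 1.75, si:ch73-359m17.9 at 1.84 and 1.35, cldng at -1.29 and 1 without a gene name at -1.26 (adjusted p = 0.00887 to 0.0456), and none passed over all arrays (adjusted p = 0.239 to 0.314). No list member passed when adjusted over the list alone, and 28 did with the replicate number as a block, among them 16 of skeletal muscle and 8 of glycolysis. The rest were hspb8, hsp90aa1.1 and hspb1 of the heat shock list and mpx of the myeloid list. Each of these was higher with MO-2, although the heat shock list was called lower. The 28 members are 26 genes, since gapdh and eno3 stand in both the muscle and glycolysis lists. Of the 7 list calls, those of oxidative phosphorylation and glycolysis were made whichever array was left out. The oxidative phosphorylation median was 0.07 without control replicate 1 and 0.28 without control replicate 4. Liver, gut and yolk genes stayed called at -0.04 and -0.08 without control replicates 1 and 3, and at -0.03 and -0.12 without MO-2 replicates 2 and 3. Leaving out MO-2 replicate 4 ended 3 calls, control replicate 2 or 3 or MO-2 replicate 1 or 2 ended 2 each, and control replicate 1 or 4, MO-2 replicate 3 or MO-1 replicate 4 ended 1 each. The muscle median was 0.20 without control replicate 3 and 0.37 without MO-2 replicate 4. The neural median was -0.03 without control replicate 1 and -0.15 without MO-2 replicate 2, and the ribosomal median -0.03 without MO-2 replicate 4. The liver, gut and yolk median was 0.01 without MO-2 replicate 1 and 0.01 without control replicate 4. The heat shock median was -0.11 without control replicate 2, -0.08 without MO-2 replicate 3 and -0.11 without MO-1 replicate 4. The arrays numbered 4 left out together ended the ribosomal call (adjusted p = 0.0581) and the liver, gut and yolk call, whose median turned to 0.05 (adjusted p = 0.382). They moved the neural median to -0.42 and the heat shock median to -0.18.

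Both morpholinos together, 8 arrays, were compared with the 4 control arrays to find changes shared by the independent oligonucleotides. The hormone genes sst1.1 and ins had the lowest p-values along with syncripl and hif1al2, and none passed (adjusted p = 1). The signal of hif1al2 lay below the lower quartile on every array. The 95% interval of the change of sst1.1 ran from -1.44 to -0.56 (SE 0.20). The other changes were -1.54 (SE 0.38) for ins, -0.50 (SE 0.11) for syncripl, -0.58 (SE 0.13) for hif1al2 and -0.97 (SE 0.24) for si:ch211-250g4.3. For syncripl the log2 signal was 9.83 ± 0.04 in control, 9.36 ± 0.20 with MO-1 and 9.30 ± 0.11 with MO-2 (SD, n = 4 each). Insulin was at 9.17 ± 0.58 and si:ch211-250g4.3 at 8.18 ± 0.24 with MO-2, against 10.67 ± 0.39 and 9.35 ± 0.14 in control (SD, n = 4 each). The change of spred1 was 0.12 (SE 0.13), and its other 3 probe sets had changes of -0.08, -0.20 and 0.05. Limma called 0 of 15502 probe sets, with 293 at an unadjusted p under 0.05; with the replicate number as a block it called 0, with 849, and without the arrays numbered 4 it called 1, pierce1, at 1.25 (adjusted p = 0.0324), chosen after its values were seen and at 0.99 (SE 0.34) over all arrays. With the block as well it called 2, pierce1 and si:ch73-359m17.9 at 1.43 (adjusted p = 0.0198 each).

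**Figure D2:**
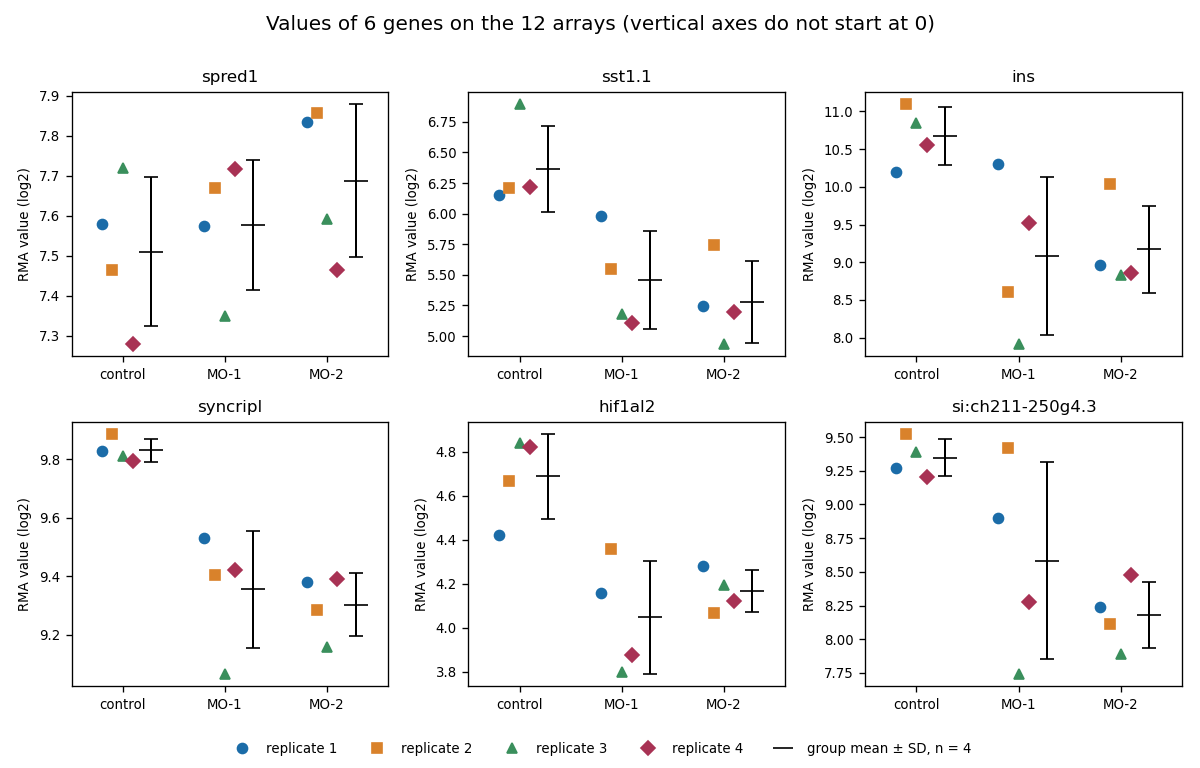
Log2 signal of named genes on each array, by group; points are arrays, with shape and colour for the replicate number, and the black bar is the group mean with its SD (n = 4); the vertical axes do not start at 0. Log2 signal of sst1.1 averages 6.37 in control, 5.46 with MO-1 and 5.28 with MO-2, and none of these genes passed the test.

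As lists, 3 were called higher and 8 lower with both morpholinos together. Oxidative phosphorylation rose by a median of 0.15 with 69 of 76 genes higher (adjusted p = 7.82e-07, and adjusted p = 0.73 with an estimated correlation). The change of cox4i1l was 0.44 (SE 0.38) and that of ndufv2 was 0.39 (SE 0.22). Glycolysis rose by 0.15 with 29 of 40 higher and a higher score in 4 of 4 pairs (adjusted p = 0.00193, and adjusted p = 0.73 with an estimated correlation). The change of aldoab was 0.74 (SE 0.70) and that of gapdh was 0.61 (SE 0.58). Skeletal muscle rose by 0.32 with 31 of 32 higher (adjusted p = 0.00693, and adjusted p = 0.776 with an estimated correlation). With MO-1 alone the muscle median was 0.03, with 17 of 32 higher, and did not pass (adjusted p = 0.75). The change of smyhc1 was 0.84 (SE 0.52) and that of the alpha-actin gene actc1a was 0.82 (SE 0.58). Neural genes fell, with a median change of -0.20 and 32 of 43 lower (adjusted p = 0.000863, and adjusted p = 0.73 with an estimated correlation). The change of sox19a was -0.66 (SE 0.25) and that of snap25a was -0.60 (SE 0.39). Erythroid genes fell, with a median change of -0.12 and 12 of 15 lower (adjusted p = 0.00483, and adjusted p = 0.73 with an estimated correlation). With MO-2 alone the erythroid median was -0.01, with 9 of 15 lower, and did not pass (adjusted p = 0.497). The change of hbbe2 was -0.65 (SE 0.34) and that of alas2, the haem synthesis enzyme of red cells, was -0.58 (SE 0.41). Ribosomal protein genes fell, with a median change of -0.06 and 64 of 74 lower (adjusted p = 0.000863, and adjusted p = 0.739 with an estimated correlation). The change of rps27l was 0.44 and that of rps10 was -0.19. Epidermal genes fell, with a median change of -0.13 and 21 of 31 lower (adjusted p = 0.00853, and adjusted p = 0.73 with an estimated correlation). The change of the keratin gene krt1-19e was 0.44 (SE 0.84) and that of the claudin gene cldni was -0.41 (SE 0.23). Liver, gut and yolk genes had a median of -0.03, a mean of -0.17 and 27 of 47 lower (adjusted p = 0.00621, and adjusted p = 0.73 with an estimated correlation). The change of ins was -1.54 and that of fga was -1.47 (SE 0.50).

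Among vascular genes, the VEGF and ERK list fell, with a median change of -0.06 and 15 of 23 lower (adjusted p = 0.0184, and adjusted p = 0.73 with an estimated correlation). The change of spry4 was -0.41 (SE 0.18) and that of the adaptor gene grb2b was -0.31 (SE 0.14). Axon guidance genes fell, with a median change of -0.07 and 20 of 30 lower (adjusted p = 0.0184, and adjusted p = 0.73 with an estimated correlation). The change of robo2 was -0.47 (SE 0.20) and that of the semaphorin gene sema3aa was -0.37 (SE 0.15). The list of heat shock and early stress fell, with a median change of -0.10 and 23 of 29 lower (adjusted p = 0.0291, and adjusted p = 0.73 with an estimated correlation), while hsp90aa1.1 was at 0.63 (SE 0.46) and hspb8 at 0.61 (SE 0.31); with the replicate number as a block its adjusted p was 0.0906. The pan-endothelial genes had a median change of 0.17, with 12 of 14 higher, and did not pass (adjusted p = 0.303); plvapb was at 0.31 (SE 0.62) and lmo2 at 0.28 (SE 0.27). Without the arrays numbered 4 they were called higher, at 0.31 with 12 of 14 higher (adjusted p = 1.84e-05, and adjusted p = 0.392 with an estimated correlation). They were also called without MO-1 replicate 4 alone and without MO-2 replicate 4 alone, at 0.30 each (adjusted p = 0.713 and 0.75 with an estimated correlation). The median was reversed without control replicate 4, at -0.04, and the direction of the test without the arrays numbered 3, at 0.08. As with each morpholino alone, the arrays numbered 4 stood out by the tested score, so calls made without them give no support for a rise. The literature targets of miR-126 had a median of 0.07 and did not pass (adjusted p = 0.209), with cxcl12b at 0.39 (SE 0.44) and hoxa9b at 0.38 (SE 0.15). No list member passed when adjusted over the list alone, and 10 did with the replicate number as a block: rhoab, hsp90aa1.1, hspb1, hspb8, gpib, tfa, fga, ins, mpx and sox19a. Each of the 11 calls was lost when some array was left out. Control replicate 1, control replicate 3 or MO-2 replicate 4 ended 5 calls each, MO-1 replicate 2 ended 4, control replicate 2 or 4, MO-1 replicate 3 or MO-2 replicate 1 ended 3 each, and MO-1 replicate 1 or 4 or MO-2 replicate 3 ended 2 each. The oxidative phosphorylation median was 0.06 without control replicate 1, the neural median 0.00 without it and -0.10 without MO-1 replicate 3. The glycolysis median was 0.10 without control replicate 3. The muscle median was -0.14 without control replicate 3, 0.15 and 0.17 without MO-1 replicates 2 and 4 and 0.20 without MO-2 replicate 4. The ribosomal median was -0.02 without MO-1 replicate 2, and the epidermal median -0.03 without MO-1 replicate 1, -0.06 without MO-2 replicate 1, -0.02 without control replicate 2 and 0.02 without control replicate 4. The VEGF and ERK median was -0.04 without control replicate 3, -0.03 without MO-1 replicate 3 and -0.02 and -0.04 without MO-2 replicates 3 and 4. The erythroid call ended at -0.19 without control replicate 4 (adjusted p = 0.0509) and at -0.15 without MO-2 replicate 4 (adjusted p = 0.0559). The heat shock median was -0.03 without control replicate 3. The axon guidance median was -0.02 and -0.01 without control replicates 1 and 3 and -0.04 without MO-1 replicate 2 or MO-2 replicate 4. Calls that were kept moved too. Without control replicate 4 the medians were -0.12 for VEGF and ERK, 0.55 for muscle, -0.31 for neural genes, 0.25 for oxidative phosphorylation and -0.12 for axon guidance. Erythroid genes were at -0.32 without control replicate 1, at -0.37, -0.35 and -0.22 without MO-1 replicates 1, 2 and 4 and at -0.34 without MO-2 replicate 1. Muscle genes were at 0.52 without control replicate 2 and 0.52 without MO-1 replicate 3, and epidermal genes at -0.31, -0.08 and -0.22 without control replicate 1 and MO-2 replicates 3 and 4. Without control replicate 2 axon guidance was at -0.10, without MO-1 replicate 2 VEGF and ERK at -0.11, and without MO-2 replicate 4 ribosomal genes at -0.03. Liver, gut and yolk genes were at -0.06, -0.07 and -0.06 without control replicate 3, MO-2 replicate 3 and MO-1 replicate 4. Their call ended, with the median turned to 0.03, 0.02 and 0.01, without MO-1 replicate 2, control replicate 4 and MO-2 replicate 1. The arrays numbered 4 left out together ended the erythroid call, at -0.05 (adjusted p = 0.219), the muscle call, at 0.35 (adjusted p = 0.063), and the ribosomal call, at -0.03 (adjusted p = 0.0535). They moved the medians of kept calls to -0.40 for neural genes, -0.13 for VEGF and ERK, -0.10 for axon guidance and 0.22 for oxidative phosphorylation.

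MO-2 was compared with MO-1 to find where the oligonucleotides differ. Skeletal muscle genes were higher with MO-2 in 32 of 32 cases, with a median difference of 0.70 (adjusted p = 4.95e-13 by camera, and adjusted p = 0.678 with an estimated correlation) and a higher score in 4 of 4 same-numbered pairs. The skeletal actin gene acta1a was at 1.24 (SE 0.70) and pgam2 at 1.05 (SE 0.82). Erythroid genes were higher by a median of 0.28 with 14 of 15 higher (adjusted p = 2.19e-05, and adjusted p = 0.501 with an estimated correlation). The change of the globin gene hbbe3 was 0.82 (SE 1.39) and that of hbbe2 was 0.81 (SE 0.39). Glycolysis genes were higher by 0.14 with 32 of 40 higher and in 4 of 4 pairs (adjusted p = 6.15e-05, and adjusted p = 0.501 with an estimated correlation). The change of aldoab was 0.92 (SE 0.80) and that of gapdh was 0.83 (SE 0.67). Mesenchymal and mural genes were higher by 0.09 with 16 of 24 higher (adjusted p = 0.0133, and adjusted p = 0.392 with an estimated correlation). The change of the fin fold gene and1 was 0.69 (SE 0.56) and that of the collagen gene col2a1a was 0.67 (SE 0.60). Genes of oxidative phosphorylation were higher by 0.06 with 57 of 76 higher (adjusted p = 0.0133, and adjusted p = 0.973 with an estimated correlation). The change of ndufa4b was 0.52 (SE 0.48) and that of cox4i2 was 0.42 (SE 0.19). Limma called 0 of 15502 probe sets between MO-2 and MO-1, with 87 at an unadjusted p under 0.05, and 0 with the replicate number as a block, with 354. The genes with the smallest p, none of which passed (adjusted p = 1), were LOC798191 at -0.48 (SE 0.13), the splicing factor gene rbm22 at 0.52 (SE 0.15), dcaf15, a substrate receptor of a ubiquitin ligase, at -0.46 (SE 0.14), the mitochondrial chaperonin gene hspe1 at -0.43 (SE 0.14) and the kinetochore gene nsl1 at -0.38 (SE 0.13). Each had the same sign in 4 of 4 pairs. No list member passed when adjusted over the list alone, and 16 did with the replicate number as a block, each a muscle gene. Of the 5 list calls that of skeletal muscle was made whichever array was left out, with a median of 0.33 without MO-1 replicate 3, 0.38 without MO-1 replicate 1 and 0.38 without MO-2 replicate 4. Other calls were kept with erythroid medians of 0.14, 0.43 and 0.66 without MO-2 replicate 1, MO-2 replicate 4 and MO-1 replicate 2. Without MO-2 replicate 2 the medians were 0.17 for mesenchymal genes and 0.09 for glycolysis, and oxidative phosphorylation was at 0.10 without MO-2 replicate 1. Leaving out MO-1 replicate 3 or MO-2 replicate 4 ended 3 calls each, and MO-1 replicate 1 or 2 or MO-2 replicate 2 or 3 ended 1 each. The glycolysis median was 0.08 and 0.09 without the first pair of arrays, and the erythroid median 0.19 without MO-1 replicate 3. The oxidative phosphorylation median was -0.03 without MO-1 replicate 1, -0.01 without MO-2 replicate 2 and 0.02 without MO-2 replicate 4. The mesenchymal median was 0.01 without MO-1 replicate 2 and 0.07 without MO-2 replicate 3. With the arrays numbered 4 left out together the 5 calls were kept, and venous and lymphatic genes at 0.15, cardiac genes at 0.27 and liver, gut and yolk genes at 0.13 were called too (adjusted p = 0.659, 0.659 and 0.822 with an estimated correlation).

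The changes with MO-1 and with MO-2 were compared across genes to ask how far the oligonucleotides act alike. Neural, ribosomal, and liver, gut and yolk lists were called lower with both morpholinos and the list of oxidative phosphorylation was called higher with both. This makes 4 lists called with the same direction and 0 with opposite directions, against the same control arrays. Liver, gut and yolk genes had medians of only -0.03 with MO-1 and -0.02 with MO-2, with 26 and 27 of 47 lower, so most of that list moved little. Without the arrays numbered 4 its MO-2 median was 0.05 and was not called. With the replicate number as a block the ribosomal call with MO-1 was lost (adjusted p = 0.0511), which leaves 3. With an estimated correlation none of these calls held, with adjusted p = 0.762 to 0.863 with MO-1 and adjusted p = 0.86 with MO-2. Across 15502 probe sets, which are not independent replicates, the log2 changes correlated with r = 0.669, and 75.1% had the same sign. Because both comparisons share the controls, unchanged groups were simulated by shuffling all arrays after centring on group means. Each draw had its own shared controls in place of the real ones, and the pairing by replicate number was not kept. These groups gave a mean r of 0.481, with 95% of the draws between -0.05 and 0.85. The same sign was seen in a mean of 66.8% (49.05 to 82.86). The covariance was 0.0238, below the simulated mean of 0.0326 (-0.0029 to 0.0833), but above the mean of 0.0179 of groups simulated with the spread left by the block. The sign of the difference thus depends on the simulation, and agreement beyond the shared controls stays open. With the controls split between the morpholinos, r averaged -0.01, from -0.19 to 0.19. In that split a pattern by replicate number enters both comparisons with opposite signs, which lowers r. With the replicate numbers split, so that each morpholino was compared with the controls of its own numbers, r averaged 0.14, from 0.03 to 0.28. No probe set was called by limma with both morpholinos, where 0 are expected of independent lists. At an unadjusted p under 0.05, 53 had the same sign with both, against 1.95 expected of independent lists and a mean of 162.4 in simulated unchanged groups, from 0 to 1181 over 100 draws. These draws came from the same shuffling, so the count does not decide.

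**Figure D3:**
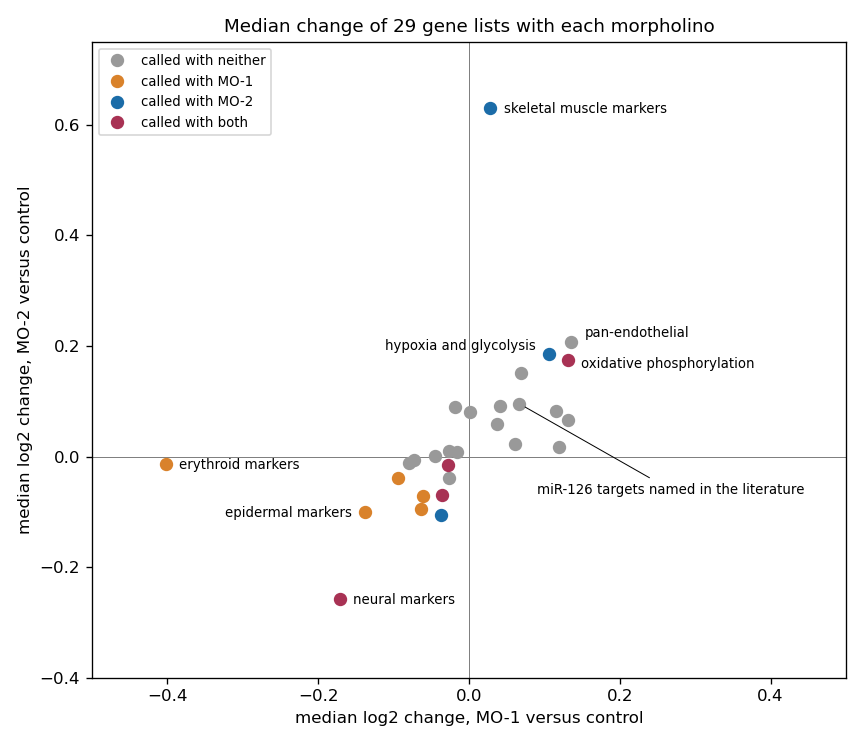
Median log2 change of each gene list with MO-1 (horizontal axis) and with MO-2 (vertical axis) against control; each point is a list, and lists called with MO-1, MO-2 or both are coloured. Skeletal muscle genes have medians of 0.03 with MO-1 and 0.63 with MO-2, and erythroid genes have -0.40 with MO-1.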

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

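The tests of muscle RNA against the glycolysis list, of liver cells, of falls by signal, and of splits of the samples for counts of probe sets were chosen only after the result was seen, and the others below were written before. For the endocrine and liver tests, the condition that most members must lie above the median signal was added after their values were seen. Without that condition the liver median had counted against fewer liver cells. Of 102 groups of 4 arrays, 4 held an array far from the others by Dixon's criterion, and chance alone gives 5.1.

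The pan-endothelial score of MO-2 replicate 4 was -0.873, against 0.331 to 0.5203 in the other MO-2 arrays, and the endothelial score of the arrays numbered 4 differed from the mean of numbers 1 to 3 by -0.56 in control, -1.25 with MO-1 and -1.29 with MO-2. More cells of other types in these sorts could lower it, though the sort on GFP is meant to remove cells without it. Of 4 marker lists, 2 were higher by over 0.2 log2, skeletal muscle by 1.13 and epidermis by 0.55. Neural (0.09) and mesenchymal (0.07) lists moved little, which argues against an equal rise of every other type. The arrays numbered 2 had high muscle scores with no fall of endothelial genes, which argues against muscle alone. Degraded RNA stays open too, since the 3′ signal of GAPDH and acta1 over the 5′ signal was higher in the arrays numbered 4 by 0.5985 log2 (SD 0.21 over the groups). Fewer GFP-positive cells cannot be told apart from the others: the EGFP control probe set differed by -0.1485 log2 (SD 0.45), from -0.60 to 0.29 by group, and whether it matches the transgene is not known. No biological explanation was tested, since each group holds 1 array numbered 4.

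Skeletal muscle and glycolysis genes were higher with MO-2 than with control, and MO-2 differed from MO-1 in a direct test by 0.6959 log2 for skeletal muscle (adjusted p = 0.678 with an estimated correlation) and 0.1431 for hypoxia and glycolysis (adjusted p = 0.501 with an estimated correlation). A few arrays may carry the muscle shift: the pair numbered 3 gave a share of 0.5609 of the summed difference, with 1.52 against 0.29, 0.29 and 0.61 in the pairs numbered 1, 2 and 4. Muscle RNA carried along could raise glycolysis genes, though the sort on GFP is meant to remove muscle cells. With the muscle score as a covariate a share of 0.538 of the glycolysis difference was left (0.24, SE 0.12, before and 0.13, SE 0.05, after), which decides neither way. Without 7 muscle genes the share left was 0.670. An effect of MO-2 on muscle or on the metabolism of endothelial cells stays open and untested.

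Insulin, somatostatin and some liver transcripts had lower means with both morpholinos together: ins -1.54, sst1.1 with a 95% interval from -1.44 to -0.56, fga -1.47 and tfa, the iron carrier transferrin, chosen after its values were seen, -1.27 (SE 0.41), none of which passed limma's test. Fewer pancreatic endocrine cells in the morpholino sorts could account for the hormones, though the sort on GFP is meant to remove them and liver cells. Even so, ins was at 10.19 to 11.09 in the control arrays, above the upper quartiles of 8.12 to 8.24. Insulin RNA was thus present in the sorted samples. The other 13 measured genes of the endocrine pancreas had a median change of -0.0503 log2. That is above the -0.1 set against this explanation by less than their SD of 0.26 over the pairs. Of these genes, 10 lay below the median signal of all probe sets, 6.83. The 3 above it, glucagon gcga and sst2 among them, were all lower, with a median of -0.46 (SD 0.40). Fewer liver cells are left open because of low signal alone: the other 33 liver genes had a median of 0.03677, 29 of them lay below the median signal, and of the 4 above it 1 was lower (median 0.13, SD 0.25). Falls by over 0.3 log2 were fewer at low signal but occurred there, with 192 of 7751 probe sets below the median signal and 364 of 7751 above it, and sst1.1 was at 6.37 in control, so that -0.1 is a weak bound for liver cells rather than one shown to be wrong. Both explanations cannot be told apart from lower expression of these genes in the injected embryos, which these data do not test.

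Other single arrays that stood apart were control replicate 3 for sst1.1, at 6.893 log2 against 6.151 to 6.22, MO-2 replicate 2 for ins, at 10.04 against 8.834 to 8.968, and MO-1 replicate 3 for dcaf15, at 8.048 against 7.505 to 7.584. A further 3 lists differed between MO-2 and MO-1 in the direct test: erythroid genes by 0.2832, mesenchymal and mural genes by 0.0929 and oxidative phosphorylation by 0.06086. With an estimated correlation these calls were lost (adjusted p = 0.501, 0.392 and 0.973).

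Chance cannot be excluded for any count of lists. For probe sets the comparison says nothing, since a real count of 0 is reached by every split (35 of 35 with MO-1, with MO-2 and between the morpholinos, and 100 of 100 with both together and for calls shared by both morpholinos). The highest other counts were 35 with MO-1, 0 with MO-2, 98 with both together, 0 between the morpholinos and 16 for shared calls. The splits with 35 and 98 set control and MO-1 replicates 1 and 3 against the rest, which points to a structure by replicate number. For lists, 24 of 35 splits gave as many as the 9 called with MO-1 (highest other 15), 22 of 35 as many as the 7 with MO-2 (13), 30 of 100 as many as the 11 with both together (17) and 31 of 35 as many as the 5 between the morpholinos (16). Of the splits that part as many same-numbered pairs as the real one, 4 of 8 gave as many lists with MO-1 (highest other 15), 3 of 8 with MO-2 (8), 2 of 13 with both together (11) and 6 of 8 between the morpholinos (7). No such split called a probe set, and the others join arrays of the same number in 1 group.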

How the results depend on the processing

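The block without the arrays numbered 4, the block with estimated correlations and the glycolysis list without muscle genes were chosen after seeing the data. Apart from single arrays and replicate numbers left out, 308 list results kept direction and side of the threshold. Another 94 were no longer called, 5 became called and 1 reversed. Of gene values and list counts under these settings, 867 stayed, 11 list counts moved and 1 gene value reversed. A gene value that stayed kept its sign, though its size could change. For probe set counts, 42 stayed and 2 moved. With arrays left out, 456 list results kept both direction and side, 124 were no longer called, 9 became called and 19 reversed. Of gene values and list counts, 1609 stayed, 12 list counts moved and 11 gene values reversed. With the replicate number as a block, which uses the pairing seen in the values, the calls of ribosomal genes with MO-1 (adjusted p = 0.0511) and of heat shock genes with MO-2 (0.0895) and both together (0.0906) were lost; of the 29 fixed lists it changed no other call. Of the lists added later, pronephros and ionocyte became called with MO-2 (0.00891) and both together (0.0183) and exocrine pancreas with MO-2 (0.0248), all lost with block and estimated correlation (0.433, 0.38 and 0.508). The seed-match test and its alternatives were not run, for want of 3′ untranslated sequences, and fitting only the groups compared does not apply to both morpholinos together. Low signal over background limits dim genes: RMA compresses changes there, and absence from this text does not show that a gene stayed the same.

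With an estimated correlation 0 lists were called in each of the 4 comparisons, with or without the block; the estimate allows for members that vary together. Array weights gave 12 lists with MO-2 and 8 between the morpholinos, an agreement r of 0.5796 and a pan-endothelial median of -0.0668 with MO-1, reversed; the brighter probe sets gave 7 lists with both together. With the block and without the arrays numbered 4, 7 probe sets were called with MO-2 and 2 with both together, and spred1 with MO-1 was reversed at -0.05682. With the controls split the agreement averaged -0.007285 (-0.1918 to 0.186), a range that spans both signs, so it is no reversal. In that split a pattern by replicate number enters both comparisons with opposite signs, which lowers r. With the replicate numbers split, which shares no control either, the agreement was 0.1413 (0.03079 to 0.2789) and did not reverse. The causes of the other changes were not tested.

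With arrays left out, lists called ranged from 3 to 13 with MO-1, 5 to 13 with both together and 4 to 9 between the morpholinos, probe sets from 0 to 1 with MO-2 and with both together, and the agreement from 0.4653 to 0.7747. Where camera's direction reversed, the list medians, which with MO-2 kept their sign, ranged with MO-1 from -0.3872 to 0.05822 (neural), -0.05602 to 0.02128 (ribosomal), -0.1148 to 0.3972 (pan-endothelial) and -0.07213 to 0.1233 (literature targets); with MO-2, from -0.4176 to -0.03074 (neural) and 0.05067 to 0.4734 (pan-endothelial); with both together, from -0.1398 to 0.5528 (muscle), -0.4024 to 0.0001593 (neural) and -0.03748 to 0.3086 (pan-endothelial); and between the morpholinos from -0.03108 to 0.1022 (oxidative phosphorylation). Genes that reversed ranged, with MO-1, from -0.05682 to 0.212 (spred1), -0.08254 to 0.6467 (lmo2), -0.9557 to 0.04953 (anxa1b) and -0.9844 to 0.2072 (krt5); with both together, from -0.3616 to 0.9696 (krt1-19e) and -0.08604 to 0.673 (plvapb); and between the morpholinos from -0.09998 to 2.108 (hbbe3) and -0.05684 to 0.9841 (col2a1a). The cause was not tested.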

Other observations

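The gene lists added here, motile cilia, pronephros and ionocyte, endocrine and exocrine pancreas and liver secreted proteins, were chosen after the smallest p-values were seen, without the genes seen there, and the predictions for the cilia and pronephros tests were written before their result. Motile cilia genes were higher with both morpholinos together: 42 of 44 measured genes had a higher mean than in control, with a median change of 0.17 log2 (adjusted p = 2.02e-08 by camera over the added lists, and adjusted p = 0.337 with an estimated correlation), at 0.15 with MO-1 and 0.18 with MO-2, and the score was higher in 3 of 4 same-numbered pairs. Members chosen after their values were seen include capsla at 0.50, cfap52 at 0.42, stk36 at 0.37 and spag6 at 0.36. Exocrine pancreas genes were higher by a median of 0.14 with 14 of 18 higher (adjusted p = 0.0378, and adjusted p = 0.433 with an estimated correlation). Endocrine pancreas genes, at -0.05, and liver secreted proteins, at 0.04, did not pass (adjusted p = 0.0947 and 0.341).

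Vascular lists that did not pass with both morpholinos together had small medians: -0.01 for arterial and Notch genes (adjusted p = 0.427), 0.05 for venous and lymphatic genes (0.72), -0.08 for PI3K, AKT and angiopoietin (0.0503), -0.03 for endothelial junctions (0.215), -0.02 for flow-responsive genes (0.685) and 0.02 for extracellular matrix (0.685). In the junction list rhoab was at -0.51 (SE 0.14) and jam3b at 0.45 (SE 0.28). Growth and stress lists had medians of -0.03 for the cell cycle (0.32), -0.02 for the p53 response (0.901) and 0.06 for interferon (0.859). Markers of other cells had 0.07 for myeloid cells (0.204), -0.00 for haematopoietic stem cells (0.859), 0.12 for heart (0.242), 0.11 for eye and lens (0.0757), 0.09 for pigment cells (0.303) and 0.06 for mesenchyme (0.56), and chemokine, TGF-beta and BMP signalling had 0.05 (0.685). The myeloperoxidase gene mpx, a neutrophil marker, was at 0.82 (SE 0.34) with MO-2. Without the arrays numbered 4, myeloid genes were called higher with MO-1, at 0.21 (adjusted p = 0.00659), and with both together, at 0.20 (0.0124), and cardiac genes with MO-2, at 0.32 (0.0032), and with both together, at 0.19 (0.0235). With an estimated correlation these calls were lost (adjusted p = 0.609 and 0.663 for myeloid genes, 0.634 and 0.58 for cardiac genes).

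More ciliated cells in the morpholino sorts may account for the cilia genes: the other genes of the list had a median change of 0.1654 log2, above the 0.1 set for it. The list was added because cilia genes stood among the smallest p-values of these same arrays. A rise of cilia genes inside the sorted cells would give the same median, so the test does not tell them apart. Motile cilia line the pronephric ducts, and the sort on GFP is meant to remove cells without it. An effect of the morpholinos on cilia genes inside the sorted cells stays open, and the call was lost with an estimated correlation.

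More pronephric or ionocyte cells in the morpholino sorts could account for slc12a3, though the sort on GFP is meant to remove such cells. The gene slc12a3, a salt cotransporter of the kidney tubule, was chosen after its values were seen and was at 0.95 (SE 0.46) with both together. The other genes of the pronephros and ionocyte list had a median change of 0.1316 log2 with 21 of 28 higher. Camera did not call it without the replicate number as a block and called it with the block, where the adjusted p was 0.0183, and adjusted p = 0.38 with an estimated correlation, so that the test does not decide.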
